A study of Mus musculus with 19 samples.

How the data were processed

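RNA was sequenced from YFP-positive Tregs of Foxp3-CRE-YFP mice with or without floxed Rela (p65) or Rel (c-Rel) alleles, in 19 libraries. The stimulated set held 6 libraries: WT with water, WT with pentoxifylline and c-Rel-deficient, 2 each. The sorted set held 13 libraries of rTregs and aTregs, with 3 in WT aTregs and 2 in every other group. The submitters' processing notes name STAR, mm10 and DESeq2 1.10.1.

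The authors deposited 1 table per set with RPKM per library, and per the file headers log2 fold changes and p-values of the authors' comparisons. The deposited values of the sorted set are RPKM after an adjustment that the headers do not describe, and its model terms are not stated. In that set 2.53% of values lie below 0 (lowest -30.7). There 15883 values are tied between the 26 pairs of libraries with the same replicate number and 0 between the 52 pairs with different numbers. Gene means differ between numbers 2 and 1 with an SD of 0.0576 on the log2 scale over 7891 genes, against 0.439 between subsets, so the adjustment acts on replicate numbers. Numbers in the deposited tables use decimal commas, which were read as points.

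The tables list 14310 and 14839 genes. In 20 and 21 of these a date stands in place of a symbol and no library values are given; they were left out. All per-sample columns were used. Relative depth in the stimulated set was read from whole-read steps, which 96.8% of 2282 genes with mean RPKM under 0.1 showed within 0.02. Depth in the sorted set could not be read, so the precision of its low values is unknown. Between 9469 and 9751 genes reached 1 RPKM in the stimulated libraries, and between 9765 and 10317 in the sorted libraries.

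Values below 0 were set to 0, 0.5 was added and log2 taken. Genes with at least 1 RPKM in at least 2 libraries of a set were tested, 9945 and 10656. Group means were compared in limma 3.58.1 (lmFit, contrasts, eBayes with trend, statmod 1.5.0, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The deposited p-values were adjusted by Benjamini-Hochberg here. Tables were read with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.

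The 13 gene lists, written from general knowledge, were Treg identity, effector Treg, resting and lymphoid homing, NF-kB subunits and feedback targets, TCR-induced early genes, helper T cytokines and lineage factors, chemokine receptors and adhesion, cell cycle, interferon-stimulated, cAMP response and phosphodiesterases, glycolysis, cholesterol biosynthesis and apoptosis regulators. They were tested in camera with a preset correlation of 0.01 and with an estimated one, adjusted over the lists of a comparison. Marker lists of B cells, plasma cells, CD8 T cells, NK and cytotoxic cells, myeloid cells, erythroid cells, and of stress and dissociation, were given without a test. The B cell list includes the class II antigen presentation genes H2-Aa, H2-Ab1 and H2-Eb1. Similarity of changes that share controls was set beside 100 simulations of unchanged groups.

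Genes were named by a rule: the targeted genes and Foxp3 always, the 5 largest rises and falls with adjusted p under 0.05, a mean of at least 5 RPKM in the higher group and no overlap between libraries, and up to 2 members of each list. Groups, tests, lists, this rule and the alternatives were fixed before the data were examined. Chosen after the data were seen were the setting without both libraries numbered 3, the NF-kB list without Rel and Rela, the reading of replicate numbers as adjustment batches, and the use of the naming rule on the deposited p-values of comparisons without a limma call.

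Replicate numbers were checked for pairing by correlating deviations from group means. In the stimulated set these were 0.40 between water and pentoxifylline, -0.07 between water and c-Rel-deficient, and 0.12 between pentoxifylline and c-Rel-deficient libraries. In the sorted set they ranged from -0.49 to 0.44. The sorted values had been adjusted for replicate number, which itself alters these deviations, so they cannot show or exclude a pairing there. In the stimulated set no pairing held throughout. The numbers were not used as pairs in the main test of either set. The drug comparison may be paired by number, while a term for replicate number in the stimulated c-Rel comparison assumes a pairing that was not seen. Alternatives tried were pseudocounts of 0.1 and 1, no filter, 3 RPKM, median-of-ratios scaling, robust variance, only the groups compared, a replicate block, and leaving out each library. No comparison has 3 libraries in each group, so groups were not regrouped at random.

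The procedure was tested on simulated data with 100 better expressed genes changed by a log2 value of 1 or 2. Noise was normal and independent between genes and libraries, with no effect of replicate number, sex, adjustment or incomplete deletion. The rates thus hold for such simple data and may be lower for the real libraries. At 1 it recovered 92% for pentoxifylline, 92% for stimulated c-Rel loss, 84% for p65 loss in rTregs and 79% for c-Rel loss in aTregs, and at 2 it recovered 99%, 100%, 99% and 96%. False calls numbered 15, 31, 10 and 8, or 7.28%, 13.9%, 5.18% and 4.37% of all calls, the first 3 above the nominal rate. The list test called 0 unchanged lists, which says nothing of lists whose genes are correlated. Gene positions come from GENCODE M21 on GRCm38.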

Results

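Gene expression was measured by RNA sequencing in 19 libraries of mouse regulatory T cells (Tregs), the CD4 T cells that restrain immune responses. All were YFP-positive cells from mice in which the Foxp3 gene, which encodes the lineage factor of Tregs, drives Cre recombinase and yellow fluorescent protein. The labels give some of them floxed alleles of p65 or c-Rel, NF-kB subunits encoded by Rela and Rel, so that Cre removes 1 subunit in Tregs. The first set held 6 libraries of Tregs stimulated for 16 hours with anti-CD3 at 5 ug/mL, anti-CD28 at 1 ug/mL and interleukin 2 at 10 ng/mL. It had 2 wild-type (WT) libraries with water, 2 WT libraries with pentoxifylline at 500 ug/mL, a phosphodiesterase inhibitor, and 2 libraries of c-Rel-deficient Tregs. The second set held 13 libraries of Tregs taken from spleen and lymph nodes without culture, sorted by surface markers as resting cells (rTreg, CD44 low) or activated cells (aTreg, CD44 high). It had 2 WT, 2 p65-deficient and 2 c-Rel-deficient rTreg libraries, and 3 WT, 2 p65-deficient and 2 c-Rel-deficient aTreg libraries. The series design gives 30M reads per sample, and neither table gives read totals. In the stimulated set the depths relative to water replicate 1 were 0.949 in water replicate 2, 0.793 and 0.682 in the pentoxifylline libraries, and 0.915 and 0.853 in the c-Rel-deficient libraries, read from the steps between low values. In the sorted set the depth is unknown.

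Values are RPKM (read counts scaled by gene length and library size), those of the sorted set after an adjustment for replicate number that no label describes. Changes are differences of group means on a log2(RPKM + 0.5) scale, which understates changes of weakly expressed genes, and errors of means are SD. No label says that the replicates are separate animals, and p-values measure the spread between these samples. Among stimulated WT Tregs the sex-linked genes Xist and Ddx3y differed widely between replicates, both with water and with pentoxifylline (values given below). Those replicates were thus not repeats of the same cells, and their spread may include a difference of sex. In the other groups the spread may be technical. Each set was tested only within itself, and list tests in camera are given with a preset correlation of 0.01 between genes. With an estimated correlation in its place, none of the 66 list results under an adjusted p of 0.05 stayed under it.

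The targeted genes were read first as a check of the labels. Rel (chromosome 11, 23736847 to 23770970, minus strand, GRCm38) stood at 55.4 ± 0.532 RPKM (n = 2) in stimulated WT Tregs with water. In stimulated c-Rel-deficient Tregs it was 2.44 in replicate 1 and 24.96 in replicate 2, so the libraries differed in what the label names. In rTregs Rel was 15.7 ± 6.82 (n = 2) in WT and 3.38 ± 2.82 (n = 2) in c-Rel-deficient cells, and in aTregs 20.6 ± 1.81 (n = 3) and 2.29 ± 1.03 (n = 2). Every c-Rel-deficient library lay below every WT library of its kind. Rela (chromosome 19, 5637483 to 5648130, plus strand) was 64.6 ± 6.69 (n = 2) in p65-deficient and 70.2 ± 1.78 (n = 2) in WT rTregs, and 51.4 ± 6.59 (n = 2) against 64.9 ± 3.07 (n = 3) in aTregs. The log2 difference of Rela in aTregs was -0.34 (SE 0.11, limma, Benjamini-Hochberg adjusted p = 0.998), and -0.49 (adjusted p = 1) in the authors' deposited table. A value for the whole gene does not show the loss of part of a transcript, so the p65 labels could not be checked from Rela. Foxp3 (chromosome X, 7573644 to 7595245, plus strand) was 263 ± 37.3 (n = 2) in stimulated WT Tregs, 84.7 ± 18.1 (n = 2) in WT rTregs and 88.3 ± 14.6 (n = 3) in WT aTregs.

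**Figure D1:**
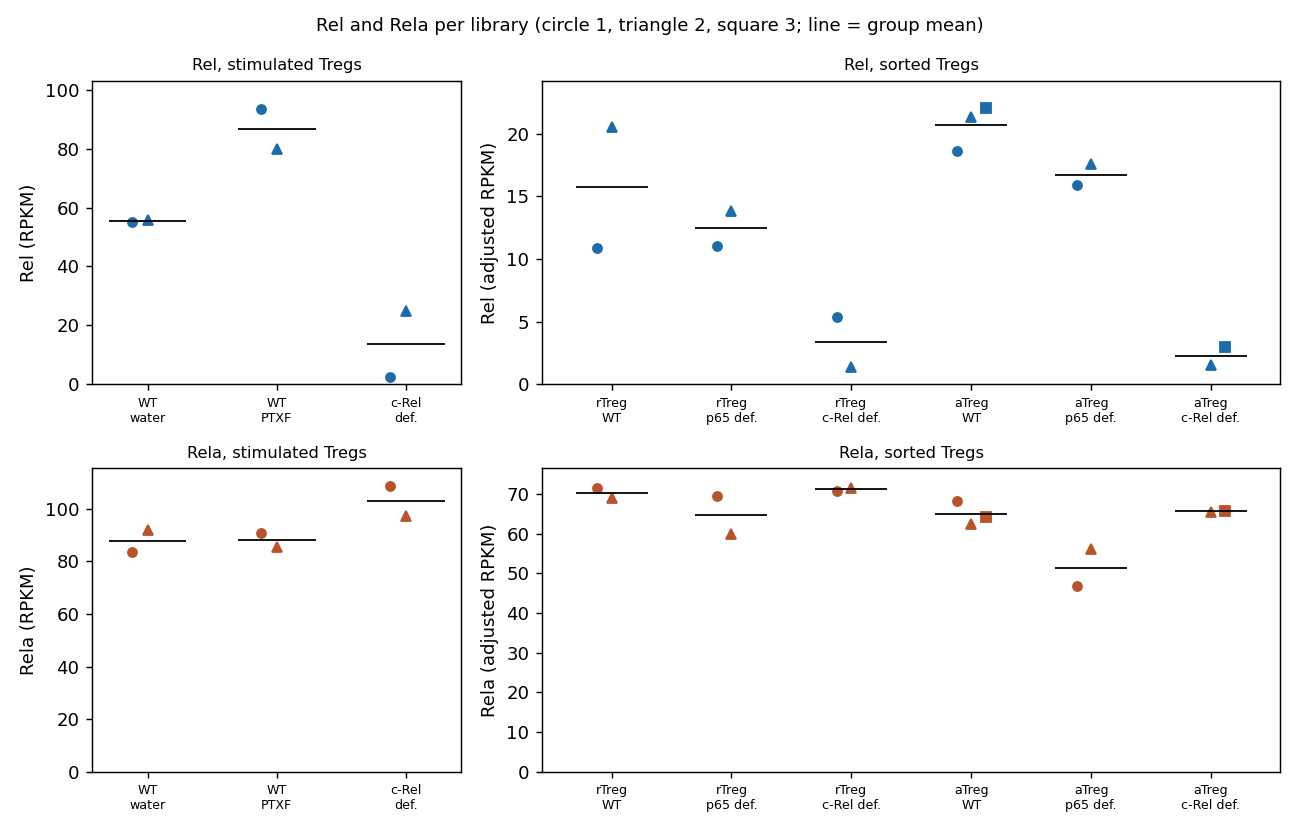
Rel and Rela in each library (vertical axis, RPKM, adjusted RPKM in the sorted set) by group (horizontal axis), with symbols for replicate numbers and a line at each group mean. Rel lies below every WT library of its kind in each c-Rel-deficient library, at 2.44 and 24.96 RPKM after stimulation, while Rela in p65-deficient aTregs is 46.8 and 56.1 against 62.3 to 68.3 in WT.

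The first comparison asks what pentoxifylline, the chemical inhibitor of the series title, does to stimulated WT Tregs. Of the 5 largest falls given by the naming rule 4 were in chemokine genes, a family that was not tested as a list. Xcl1 (chromosome 1, 164931644 to 164935527, minus strand) was 0.869 ± 0.0926 RPKM (n = 2) with the drug and 40.9 ± 19.5 (n = 2) with water, a log2 change of -4.84 (SE 0.33, limma, Benjamini-Hochberg adjusted p = 0.000523). Ccl4 changed by -5.63 (SE 0.74), Ccl3 by -5.06 (SE 0.53) and Ccl1 by -4.41 (SE 0.67). Snord69, a small nucleolar RNA, was 12.8 ± 2.72 with water and listed at 0 in both pentoxifylline libraries. Rgs2, which dampens G protein signalling, rose from 24.6 ± 3.53 to 228 ± 55.2 (log2 change 3.17, SE 0.36, adjusted p = 0.00104). Gng4, a G protein subunit, rose by 3.54 (SE 0.36), the receptor partner Ramp3 by 3.04 (SE 0.18), the sorting factor Vps37b by 3.03 (SE 0.22) and the microRNA gene Mir1943 by 3.39 (SE 0.54). The authors' deposited table does not call Snord69 (adjusted p = 0.153) or Mir1943 (adjusted p = 0.279).

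Genes that follow T cell receptor stimulation fell as a group, 15 of 22 measured members lower and 1 higher (also 15 and 1 adjusted over the list alone). Egr2, a transcription factor induced by the receptor, changed by -3.47 (SE 0.53), Spry1, a feedback inhibitor, by -2.63 (SE 0.26) and Fosl2, an AP-1 member, by 2.14 (SE 0.18). The list had a median of -1.07 (camera adjusted p = 0.00145; adjusted p = 0.572 with an estimated correlation). Of 18 helper T cytokines and lineage factors 12 fell and 1 rose (12 and 1 adjusted over the list alone), among them Tbx21, which encodes T-bet (-3.42, SE 0.36), Tnf (-3.18, SE 0.35) and Ifng (-4.14, SE 0.74). Egr2 and Ifng were chosen after their values were seen. The median of the cytokine list was -1.91 (camera adjusted p = 0.000558; adjusted p = 0.572 with an estimated correlation).

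Of 23 cell cycle genes 13 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -1.10 (camera adjusted p = 0.000558; adjusted p = 0.598 with an estimated correlation). The replicative helicase genes Mcm3 (-2.14, SE 0.24) and Mcm5 (-2.11, SE 0.24) were among those that fell, while the proliferation marker Mki67 stood at 23.2 ± 2.91 (n = 2) against 19.2 ± 3.20 (n = 2; adjusted p = 0.67). Of 15 cholesterol biosynthesis genes 11 fell (13 adjusted over the list alone), among them Sqle (-1.31, SE 0.21) and Fdps (-1.25, SE 0.19). The cholesterol median was -0.68 (camera adjusted p = 0.000558; adjusted p = 0.582 with an estimated correlation). Of 16 glycolysis genes 9 fell and 1 rose (9 and 1 adjusted over the list alone), the falls including the lactate transporter Slc16a1 (-1.77, SE 0.18) and Tpi1 (-1.31, SE 0.14). Their median was -0.71 (camera adjusted p = 0.00751; adjusted p = 0.572 with an estimated correlation). Of 19 interferon-stimulated genes 8 fell (8 adjusted over the list alone), among them Bst2 (-1.80, SE 0.24) and Gbp4 (-0.86, SE 0.14). The interferon median was -0.65 (camera adjusted p = 0.0194; adjusted p = 0.572 with an estimated correlation).

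Of 20 genes of the cyclic AMP response and phosphodiesterases 10 rose and 5 fell (11 and 5 adjusted over the list alone), median 0.80 (camera adjusted p = 0.0194; adjusted p = 0.572 with an estimated correlation). Pde2a, which degrades cyclic nucleotides, rose by 2.86 (SE 0.29), Pde4d by 2.06 (SE 0.18) and Crem, a cyclic AMP-responsive regulator chosen after its value was seen, by 1.66 (SE 0.26). Of 19 genes of resting cells and lymphoid homing 11 rose and 3 fell (11 and 3 adjusted over the list alone). They include Klf2, a quiescence factor (1.92, SE 0.17), and its target S1pr1, which directs exit from lymphoid organs (1.92, SE 0.14). Their median was 0.49 (camera adjusted p = 0.00553; adjusted p = 0.572 with an estimated correlation).

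Among 24 NF-kB subunits and feedback targets 7 fell and 3 rose (7 and 3 adjusted over the list alone; camera adjusted p = 0.299), and Tnfaip3, which encodes the NF-kB inhibitor A20, rose from 82.7 ± 3.38 to 533 ± 133 (log2 change 2.66, SE 0.19). Rel itself was 86.7 ± 9.62 with the drug (0.64, SE 0.83, adjusted p = 0.561), and the authors' deposited table calls it higher (0.62, adjusted p = 0.0248). Foxp3 was 246 ± 39.8 against 263 ± 37.3 (adjusted p = 0.802), and Rela changed by 0.01 (SE 0.14, adjusted p = 0.971). Treg identity genes went both ways, with 1 higher and 5 lower of 17 (1 and 4 adjusted over the list alone; camera adjusted p = 0.339), the falls including Gpr83 (-1.44, SE 0.23) and Capg (-1.13, SE 0.24). Effector Treg genes did too, with 6 higher and 8 lower of 25 (7 and 9 adjusted over the list alone; camera adjusted p = 0.779). Among these, Lag3, an inhibitory receptor, fell from 81.6 ± 12.9 to 8.82 ± 1.49 (-3.14, SE 0.27) and Il10, a suppressive cytokine, from 117 ± 39.2 to 19.5 ± 7.12 (-2.56, SE 0.31). Chemokine receptors and adhesion genes (5 higher and 8 lower of 26, the same counts adjusted over the list alone) included Cxcr4 (2.08, SE 0.19), with a camera adjusted p of 0.883. Apoptosis regulators (5 higher and 6 lower of 19, the same counts adjusted over the list alone) included Bcl2, which promotes survival (1.03, SE 0.13), and Bid, which promotes death (-1.46, SE 0.18), with a median of 0.23, a mean of -0.01 and a camera adjusted p of 0.853. B cell markers, which include class II antigen presentation genes, were lower in 5 of 6 detected genes (median -1.15), with H2-Ab1, chosen after its value was seen, at 2.56 ± 1.23 against 12.2 ± 2.21. The 2 detected NK and cytotoxic markers had a median of -1.84, the 4 myeloid markers one of 0.11 and the 13 stress and dissociation genes one of -0.19.

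In all, limma called 4324 of 9945 tested genes, 1950 higher and 2374 lower, and with a term for replicate number 4595, 2097 higher and 2498 lower. The authors' deposited table, with its p-values adjusted here, calls 1396 higher and 1849 lower, of which 3188 were tested in limma, all in the same direction, and 3012 called. Without water replicate 2 limma called 2217 genes and without pentoxifylline replicate 1 it called 2480. Of the 34 called genes that the naming rule gave, Capg alone then lost its call (adjusted p = 0.0535 and 0.0646).

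The second comparison asks what the loss of c-Rel does in stimulated Tregs, although replicate 2 of those labelled c-Rel-deficient held Rel at 24.96 RPKM. Ccl22, a chemokine gene (chromosome 8, 94745590 to 94751699, plus strand), was 0.236 ± 0.294 RPKM (n = 2) in the libraries labelled c-Rel-deficient and 19.0 ± 15.9 (n = 2) in WT with water, and Foxp3 was 150 ± 60.5 (n = 2) against 263 ± 37.3 (n = 2). In the authors' deposited table Ccl22 fell by 5.35 on the log2 scale (adjusted p = 9.76e-23), Foxp3 by 1.11 (adjusted p = 5.43e-05) and Rel by 3.38 (adjusted p = 2.9e-45). The same table calls the proliferation genes Mki67 (-2.08, adjusted p = 1.09e-15) and Ccna2 (-2.01, adjusted p = 4.34e-10) lower, with Klrg1, a receptor of differentiated effector cells (-1.78, adjusted p = 4.22e-06), and the TGF-beta-presenting Lrrc32 (-1.13, adjusted p = 8.33e-06). It calls Tcf7, a factor of resting and memory T cells, higher (1.52, adjusted p = 3.69e-10), as it does Eomes, a cytotoxic lineage factor (2.72, adjusted p = 6.81e-09), Pde3b, a phosphodiesterase (2.68, adjusted p = 6.82e-20), and Bcl2l11, which promotes death (1.15, adjusted p = 3.26e-05). Within replicate numbers 1 and 2 Eomes differed by 3.88 and 0.0451 in the values used here, so that 1 library carries it. Among its largest falls the authors' deposited table gives -3.16 for H2-Ab1 (adjusted p = 3.74e-09), -5.17 for the immunoglobulin joining chain gene Igj (adjusted p = 3.51e-31) and -3.47 for Rcn3 (adjusted p = 6.67e-12). Markers of other cells, not tested as lists, stood lower beside them, with 6 of 6 detected B cell markers below 0 (median -1.65), 4 of 4 myeloid markers (median -1.98), 2 of 2 plasma cell markers (median -2.54) and 2 of 2 NK and cytotoxic markers (median -0.81). Of these lists the authors' deposited table calls 4 B cell, 1 myeloid, 1 plasma cell and 1 NK and cytotoxic marker lower.

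By limma 0 of 9945 genes passed, 791 had an unadjusted p under 0.05, and with a term for replicate number 1 passed, Ccl22 (-4.50, SE 0.31, adjusted p = 0.0189). The authors' deposited table calls 69 genes higher and 237 lower, of which 296 were tested in limma and 295 had the same sign. Rel was -2.69 in limma (SE 0.83, adjusted p = 0.489), with -4.24 in replicate 1 and -1.14 in replicate 2, and Foxp3 was -0.86 (SE 0.28, adjusted p = 0.516), with -1.43 and -0.30. Without c-Rel-deficient replicate 2 limma called 280 genes, 49 higher and 231 lower, 211 of which the authors' deposited table also calls, and without c-Rel-deficient replicate 1 it called 1, Jun (-2.36, adjusted p = 0.0221).

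As a group, cell cycle genes were lower in the libraries labelled c-Rel-deficient, 21 of 23 below 0 with a median of -0.90 (camera adjusted p = 2.07e-12; adjusted p = 0.516 with an estimated correlation), 0 called and 8 lower adjusted over the list alone. Effector Treg genes had a median of -0.49 (22 of 25 below 0, 0 called, 1 lower adjusted over the list alone; camera adjusted p = 1.26e-07). Treg identity genes had a median of -0.51 (15 of 17 below 0, 0 called, 0 adjusted over the list alone; camera adjusted p = 2.61e-06). For chemokine receptors and adhesion genes the median was -0.28 (20 of 26 below 0, 0 called either way; camera adjusted p = 0.000234). Genes of resting cells and lymphoid homing were higher, 17 of 19 above 0 with a median of 0.54 (0 called, 5 higher adjusted over the list alone; camera adjusted p = 5.37e-09), and Ccr7, a receptor for lymph node homing, was called by the authors' deposited table (1.01, adjusted p = 0.000513), with differences of 1.39 in replicate 1 and 0.114 in replicate 2. Helper T cytokines and lineage factors (median 0.56, camera adjusted p = 0.0153) and early genes of T cell receptor stimulation (median 0.38, camera adjusted p = 0.0453) were higher, with 0 members called, also 0 adjusted over the list alone. All 6 lists after the first had adjusted p = 0.516 with an estimated correlation. The other lists did not pass: NF-kB subunits and targets (adjusted p = 0.665, median 0.04 but mean -0.13 and a test direction of lower), interferon-stimulated genes (0.924, median and mean above 0 with a test direction of lower), cyclic AMP genes (0.924), glycolysis (0.083), cholesterol biosynthesis (0.665, median 0.01 and mean -0.01) and apoptosis regulators (0.391), where limma called 0 members.

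**Figure D2:**
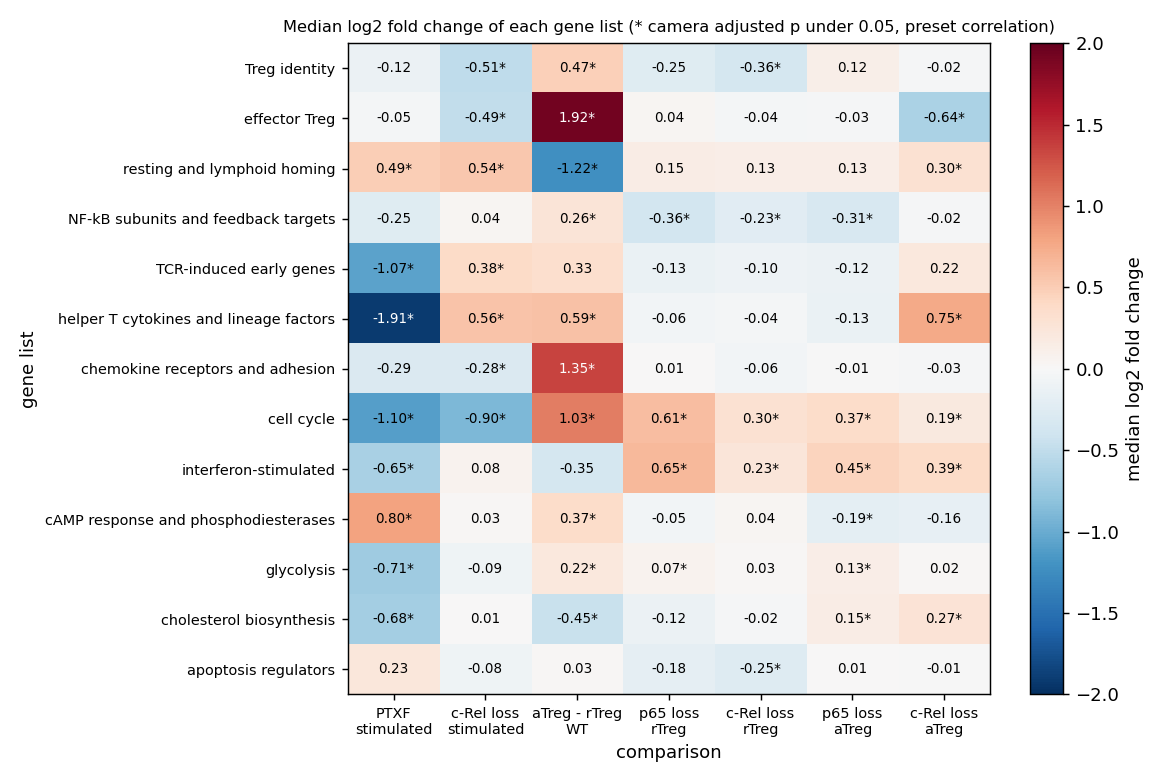
Median log2 fold change (colour and number) of the 13 gene lists (vertical axis) in 7 comparisons (horizontal axis), with a star where the camera adjusted p was under 0.05 with the preset correlation. Helper T cytokines and lineage factors stand at -1.91 with pentoxifylline and at 0.56 after c-Rel loss in stimulated Tregs, and interferon-stimulated genes above 0 in all 4 comparisons of sorted p65-deficient or c-Rel-deficient Tregs.

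The direct contrast of pentoxifylline with c-Rel loss asks whether drug and deletion left different transcripts. Ccl4 stood at 2.60 ± 3.07 RPKM (n = 2) with the drug and 140 ± 6.68 (n = 2) in c-Rel-deficient libraries (log2 difference -5.98, SE 0.74, adjusted p = 0.000937), and Crabp2, which binds retinoic acid, at 0.282 ± 0.127 and 26.9 ± 10.3 (-5.09, SE 0.49, adjusted p = 0.000436). Snord69 was listed at 0 in both drug libraries and was 14.1 ± 1.94 in c-Rel-deficient Tregs. Gng4 (4.42, SE 0.36), Rgs2 (4.10, SE 0.36) and the peptide transporter Slc15a2 (3.89, SE 0.67) were higher with the drug. Limma called 4815 genes, 2148 higher and 2667 lower with the drug, or 2307 and 2753 with a term for replicate number, and 3076 in all without pentoxifylline replicate 1. Helper T cytokines and lineage factors were lower with the drug (14 of 18 called lower and 1 higher, 15 and 1 adjusted over the list alone, median -2.38, camera adjusted p = 0.00043; adjusted p = 0.678 with an estimated correlation). So were early genes of T cell receptor stimulation (15 of 22 lower and 2 higher, the same counts adjusted over the list alone, median -1.30, camera adjusted p = 0.00193; adjusted p = 0.678 with an estimated correlation). Of 15 cholesterol genes 10 were lower, also 10 adjusted over the list alone (median -0.80, camera adjusted p = 0.00193; adjusted p = 0.761 with an estimated correlation), and the other 10 lists had camera adjusted p from 0.0648 to 0.572. Markers of other cells also stood apart, higher with the drug for myeloid (4 of 4, median 1.88), plasma cell (2 of 2, median 3.00) and B cell markers (5 of 6, median 0.96), with a median of -1.02 for the 2 NK and cytotoxic markers.

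Across 9945 genes, which are not independent replicates, the changes under pentoxifylline and under c-Rel loss had a Pearson r of -0.077. In 100 simulations of unchanged groups against shared controls r was 0.499 on average. That value is no reference here, since limma called 4324 genes under pentoxifylline and such changes pull the r from shared controls towards 0. The covariances can be compared, -0.0229 beside 0.0254 in the simulations. Within replicate numbers r was -0.143 and 0.256, and without water replicate 1 it was 0.182. The authors' deposited table calls 18 genes higher in both (6.74 for independent calls) and 49 lower in both (30.7). It calls 44 higher with the drug and lower in c-Rel-deficient libraries (23.2), and 24 the reverse (8.93). Independence leaves out the shared water libraries, which push both changes the same way (66.7% of signs equal in the simulations). They may account for part of the counts in the same direction, but not for the excess in opposite directions. The independent counts also spread over all 14290 genes of the deposited table, weakly expressed ones included, which lowers them.

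The comparison of WT aTregs with WT rTregs asks how the activated subset differs from the resting one. Klrg1 rose from 5.22 ± 1.19 RPKM (n = 2) in rTregs to 75.5 ± 11.7 (n = 3) in aTregs (log2 change 3.73, SE 0.35, adjusted p = 0.00526), and Penk, the enkephalin precursor gene, from 10.6 ± 4.35 to 125 ± 20.9 (3.54, SE 0.41, adjusted p = 0.00526). Il1r2, a decoy receptor for interleukin 1, rose by 3.83 (SE 0.59), the transporter gene Slc7a10 by 3.35 (SE 0.97) and the myosin gene Myo1f by 3.26 (SE 0.46). The largest falls were in Gabrr2 (-2.25, SE 0.63), the kinase genes Sgk3 (-1.88, SE 0.49) and Txk (-1.81, SE 0.44), the transcription factor gene Sox4 (-1.85, SE 0.50) and the tubulin gene Tubb2a (-1.82, SE 0.48). Foxp3 differed by 0.06 (SE 0.34, adjusted p = 0.915), Rel by 0.45 (SE 0.42, adjusted p = 0.481) and Rela by -0.11 (SE 0.11, adjusted p = 0.491).

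Of 25 effector Treg genes 18 rose (23 adjusted over the list alone), with Ccr8, a chemokine receptor of effector Tregs, at 79.2 ± 21.6 against 10.8 ± 3.03. The effector median was 1.92 (camera adjusted p = 2.49e-17; adjusted p = 0.15 with an estimated correlation). Of 24 cell cycle genes 10 rose (21 adjusted over the list alone), including the mitotic genes Aurkb (2.23, SE 0.42) and Ccnb1 (1.92, SE 0.35). The cell cycle median was 1.03 (camera adjusted p = 2.11e-10; adjusted p = 0.322 with an estimated correlation). Of 26 chemokine receptor and adhesion genes 9 rose and 1 fell (12 and 3 adjusted over the list alone), including the integrin gene Itgae (2.10, SE 0.36). Their median was 1.35 (camera adjusted p = 0.000508; adjusted p = 0.15 with an estimated correlation). Of 18 Treg identity genes 3 rose (6 adjusted over the list alone), Nrp1 among them (1.42, SE 0.29), median 0.47 (camera adjusted p = 0.00297; adjusted p = 0.449 with an estimated correlation). Of 19 genes of resting cells and lymphoid homing 5 fell (10 adjusted over the list alone), with Foxp1, a quiescence factor (-0.97, SE 0.18), and Klf3 (-0.77, SE 0.19). The resting median was -1.22 (camera adjusted p = 6.26e-05; adjusted p = 0.344 with an estimated correlation).

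Cholesterol genes fell in 4 of 16 members (9 adjusted over the list alone), among them Sqle (-0.86, SE 0.21) and Mvd (-0.69, SE 0.15). The cholesterol median was -0.45 (camera adjusted p = 0.00297; adjusted p = 0.322 with an estimated correlation). Glycolysis genes rose in 4 of 18 (6 higher and 2 lower adjusted over the list alone), with Slc16a3 (1.08, SE 0.24) and Tpi1 (0.68, SE 0.14). The glycolysis median was 0.22 (camera adjusted p = 0.00831; adjusted p = 0.322 with an estimated correlation). Of 18 cyclic AMP genes 3 rose and 1 fell (the same counts adjusted over the list alone), Nr4a2 by 1.38 (SE 0.31) and Pde4b by -0.53 (SE 0.13). Their median was 0.37 (camera adjusted p = 0.0109; adjusted p = 0.15 with an estimated correlation). Cytokine and lineage factor genes rose in 2 of 12, Bcl6 (1.12, SE 0.26) and Gata3 (0.86, SE 0.16) (3 adjusted over the list alone). The cytokine median was 0.59 (camera adjusted p = 0.0428, or 0.0924 after median-of-ratios scaling; adjusted p = 0.486 with an estimated correlation). NF-kB genes rose in 3 of 24 (5 higher and 1 lower adjusted over the list alone), including Cd83 (2.47, SE 0.63) and the survival gene Bcl2a1d (2.14, SE 0.61), median 0.26 (camera adjusted p = 0.0478, or 0.0659 after scaling; adjusted p = 0.486 with an estimated correlation). Early genes of T cell receptor stimulation (5 higher and 2 lower of 21, 7 and 5 adjusted over the list alone) had a camera adjusted p of 0.0659 and included Egr2 (1.29, SE 0.20) and Nfatc1 (1.27, SE 0.20). Interferon-stimulated genes (1 higher and 1 lower of 24, 1 and 0 adjusted over the list alone) had 0.167, with Oas1a at 0.77 (SE 0.18) and Ifi35 at -0.75 (SE 0.21). Apoptosis regulators (3 higher and 4 lower of 19, 5 and 6 adjusted over the list alone) had 0.988, a median and mean above 0 and a test direction of lower, with Casp8 at -0.84 (SE 0.21) and Fas at -0.60 (SE 0.14). With a term for replicate number and an estimated correlation, effector genes (adjusted p = 0.0317), resting genes (0.0448) and helper T cytokines (0.045) passed. With that term and the preset correlation early T cell receptor genes (adjusted p = 0.0227, higher) and interferon-stimulated genes (0.0152, lower) passed too. Erythroid markers stood higher in aTregs (3 of 3, median 0.76), and B cell markers had a median of -0.49 (4 of 6 lower).

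Limma called 1302 of 10656 genes, 803 higher and 499 lower in aTregs, or 895 and 352 after median-of-ratios scaling, which moved the median of all genes by 0.0692. The authors' deposited table calls 1183 higher and 483 lower, with 1367 tested in limma, all of the same sign, and 804 called. Across genes its log2 changes had a slope of 1.41 on those of limma, against 0.91 to 1.08 in the other comparisons. The sizes given here for this comparison are thus mostly smaller than the deposited ones. Of the genes named here as called it does not call Sqle (adjusted p = 0.0894), Klf3 (0.165), Mvd (0.182), Fas (0.247) or Pde4b (0.489). The libraries numbered 3, aTregs alone, lay between the subsets: the first principal component (55.9% of variance) was 40.0, 37.5 and 4.29 in WT aTreg replicates 1, 2 and 3, and -17.9 to -40.1 in the 6 rTreg libraries. With a term for replicate number limma called 1146 genes higher and 931 lower, and 1168 and 1031 without both libraries numbered 3, a setting chosen after the data were seen. Leaving out 1 library gave 84 genes without aTreg replicate 1, 92 without aTreg replicate 2, 2391 without aTreg replicate 3, 252 without rTreg replicate 1 and 2960 without rTreg replicate 2. Of the 33 genes named here as called, 26, 26, 0, 24 and 5 lost the call in the same order.

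**Figure D3:**
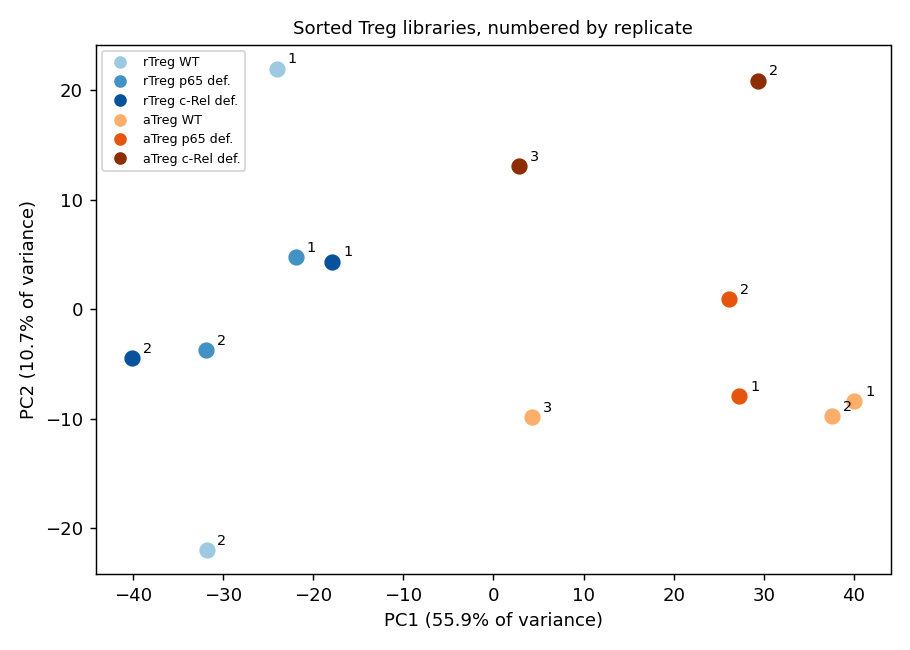
First (horizontal axis, 55.9% of variance) and second (vertical axis, 10.7% of variance) principal components of the 13 sorted libraries, coloured by group and numbered by replicate. WT aTreg replicate 3 lies at 4.29 on the first component and c-Rel-deficient aTreg replicate 3 at 2.89, below the other aTreg libraries at 26.2 to 40.0.

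The loss of p65 was compared with WT in rTregs to ask what p65 does in resting cells. The interferon-stimulated genes Ifit3 (39.3 ± 4.62 RPKM, n = 2, against 14.8 ± 3.904, n = 2) and Cmpk2 (15.5 ± 1.86 against 6.45 ± 0.0731) stood higher without p65. In the authors' deposited table Ifit3 rose by 1.38 (adjusted p = 0.0217), its paralog Ifit3b by 1.76 (adjusted p = 0.000108), Cmpk2 by 1.31 (adjusted p = 2.71e-05) and Racgap1, a gene of cytokinesis, by 1.56 (adjusted p = 0.0294). Interferon-stimulated genes were above 0 in 23 of 24 members (median 0.65, 0 called, 8 higher adjusted over the list alone; camera adjusted p = 2.07e-16). Cell cycle genes were above 0 in 24 of 24 (median 0.61, 0 called, 13 higher adjusted over the list alone; camera adjusted p = 2.05e-17). NF-kB subunits and feedback targets were below 0 in 23 of 24 (median -0.36, 0 called, 1 lower adjusted over the list alone; camera adjusted p = 1.38e-07), with Nfkbia, the gene of the inhibitor IkB-alpha, at 170 ± 1.31 against 304 ± 63.1 and Relb at 14.4 ± 0.0371 against 24.2 ± 3.26, both chosen after their values were seen. These 3 lists had adjusted p = 0.239 with an estimated correlation. Glycolysis genes were higher (median 0.07, 0 called, 1 higher adjusted over the list alone; camera adjusted p = 0.0356, or 0.0543 with a term for replicate number; adjusted p = 0.452 with an estimated correlation), and the other 9 lists had camera adjusted p from 0.241 to 0.955. Among these, chemokine receptors and adhesion genes had a median above 0 and a mean below it. The 3 detected erythroid markers stood higher beside them (median 2.52), with Hba-a2, chosen after its value was seen, at 13.03 and -3.00 in WT and 24.9 and 22.2 in p65-deficient rTregs, and the 6 detected B cell markers lower (median -0.58). Limma called 0 genes, also 0 with a term for replicate number, with 726 at an unadjusted p under 0.05 (324 without p65-deficient replicate 1, 2653 without WT replicate 2), and the authors' deposited table calls 5 higher and 0 lower.

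The loss of c-Rel in rTregs asks the same of c-Rel. In the authors' deposited table Rel fell by 2.48 (adjusted p = 4.74e-06), against -2.22 in limma (SE 0.46, adjusted p = 0.627, -0.96 and -3.48 within replicate numbers 1 and 2). The same deposited table calls Cmpk2 (1.04, adjusted p = 0.00858) and Rell1, of the RELT receptor family (1.61, adjusted p = 0.0101), higher. Foxp3 was 73.6 and 28.1 RPKM in the 2 c-Rel-deficient libraries and 71.9 and 97.5 in WT (limma log2 difference -0.87, SE 0.37, adjusted p = 0.681). Treg identity genes were lower (16 of 18 below 0, median -0.36, 0 called, 0 adjusted over the list alone; camera adjusted p = 0.000788), as were NF-kB genes (19 of 24, median -0.23, 0 called, 1 lower adjusted over the list alone, Rel itself, camera adjusted p = 0.00123, or 0.00478 and 0 genes lower without Rel and Rela, a setting chosen after the data were seen) and apoptosis regulators (15 of 19, median -0.25, 0 called either way, camera adjusted p = 0.0147). Interferon-stimulated genes were higher (22 of 24 above 0, median 0.23, 0 called, 2 higher adjusted over the list alone; camera adjusted p = 0.000113). These lists had adjusted p = 0.648 with an estimated correlation, and cell cycle genes, also higher (median 0.30, 0 called either way, camera adjusted p = 0.00123), had adjusted p = 0.836 with an estimated correlation. The other 8 lists had camera adjusted p from 0.126 to 0.931, helper T cytokines with a median below 0 and a mean above it. Erythroid markers again stood higher (3 of 3, median 2.87). Limma called 0 genes, also 0 with a term for replicate number, with 775 at an unadjusted p under 0.05 (382 without c-Rel-deficient replicate 2, 2770 without WT replicate 2), and the authors' deposited table calls 2 higher and 2 lower.

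The loss of p65 in aTregs was compared in the same way. In the authors' deposited table the NF-kB subunit gene Relb fell by 1.12 (adjusted p = 0.0149). The same deposited table calls Ctla2a (-1.80, adjusted p = 0.00958), Asb2 (-1.74, adjusted p = 0.0249) and Susd2 (-1.47, adjusted p = 0.0249) lower, and Ifit3 (1.58, adjusted p = 0.000126), Ifit1 (1.07, adjusted p = 0.0249), Cmpk2 (0.92, adjusted p = 0.00958) and Usp3 (0.55, adjusted p = 0.0381) higher. NF-kB genes were below 0 in 23 of 24 members (median -0.31, camera adjusted p = 1.95e-07; adjusted p = 0.182 with an estimated correlation), with Nfkbia, chosen after its value was seen, at 166 ± 29.2 (n = 2) against 254 ± 38.0 (n = 3). Interferon-stimulated genes were above 0 in 23 of 24 (median 0.45, camera adjusted p = 5.83e-12; adjusted p = 0.149 with an estimated correlation) and cell cycle genes in 24 of 24 (median 0.37, camera adjusted p = 1.56e-08; adjusted p = 0.353 with an estimated correlation). Glycolysis (median 0.13, camera adjusted p = 1.13e-05; adjusted p = 0.149 with an estimated correlation) and cholesterol genes (median 0.15, camera adjusted p = 0.00343; adjusted p = 0.353 with an estimated correlation) were higher, and cyclic AMP genes lower (median -0.19, camera adjusted p = 0.00769; adjusted p = 0.149 with an estimated correlation). Limma called 0 members of these lists, and 2 interferon-stimulated genes higher adjusted over the list alone. The other 7 lists had camera adjusted p from 0.0926 to 0.965. Median and mean differed in sign for chemokine receptor, effector Treg and apoptosis genes. With a term for replicate number resting genes were higher (median 0.44, adjusted p = 2.67e-09, or 0.0421 with an estimated correlation) and helper T cytokines lower (median -0.41, adjusted p = 7.89e-06, or 0.0421 with an estimated correlation). Effector Treg genes (median -0.27, adjusted p = 0.00173, or 0.162 with an estimated correlation) and early genes of T cell receptor stimulation (median -0.19, adjusted p = 0.0166, or 0.385) were then lower too. Erythroid markers stood higher (3 of 3, median 1.47). Limma called 0 genes, with 365 at an unadjusted p under 0.05, and with a term for replicate number 1, Igfbp4, which binds insulin-like growth factors (2.00, adjusted p = 0.0314), but 0 without both libraries numbered 3. It called 1 gene without p65-deficient replicate 1, Ifi208, and 2 without p65-deficient replicate 2, Snord110 and Hist1h4d, named because the counts are small. The authors' deposited table calls 10 higher and 19 lower.

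The loss of c-Rel in aTregs was compared last against WT. Effector genes stood lower: Klrg1 was 15.9 ± 11.1 RPKM (n = 2) without c-Rel and 75.5 ± 11.7 (n = 3) with it, Penk 41.1 ± 23.1 against 125 ± 20.9 and Ccr8 27.8 ± 17.2 against 79.2 ± 21.6 (Klrg1 and Ccr8 chosen after their values were seen). In the authors' deposited table Penk fell by 1.40 (adjusted p = 0.00379), Slc7a10 by 3.25 (adjusted p = 4.09e-05), Lad1 by 2.14 (adjusted p = 0.0199), Tnfrsf8, which encodes the activation receptor CD30, by 2.03 (adjusted p = 5.74e-08) and Rel by 2.73 (adjusted p = 1.52e-09). The same deposited table calls Il21, a cytokine of helper cells (2.17, adjusted p = 0.00275), Eomes (2.54, adjusted p = 0.000571), Ifit3 (1.16, adjusted p = 0.015) and Oasl2 (1.16, adjusted p = 0.028) higher. It also calls higher the antigen presentation genes H2-Aa (2.82, adjusted p = 0.000216) and H2-Eb1 (2.83, adjusted p = 0.000451), the adaptor of myeloid and NK receptors Tyrobp (3.26, adjusted p = 1.14e-05), Klrd1 of NK cells (2.98, adjusted p = 0.000451; 5.35 and 0.497 here within numbers 2 and 3) and Ly6c2 (2.97, adjusted p = 1.89e-05). Of the marker lists, 5 of 6 B cell markers (median 2.58), 5 of 5 NK and cytotoxic markers (2.26), 3 of 3 erythroid markers (1.55) and 2 of 3 myeloid markers (0.26) stood higher. The B cell list includes the class II genes H2-Aa (3.37), H2-Ab1 (3.84) and H2-Eb1 (3.66), while its members Cd79a and Cd79b differed by -0.07 and 0.06. Foxp3 was 59.0 ± 7.82 against 88.3 ± 14.6 (limma log2 difference -0.57, SE 0.34, adjusted p = 0.843).

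Effector Treg genes were lower (19 of 25 below 0, median -0.64, 0 called, 9 lower adjusted over the list alone; camera adjusted p = 3.97e-08; adjusted p = 0.449 with an estimated correlation). Helper T cytokines and lineage factors were higher (9 of 12 above 0, median 0.75, 0 called, 3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0105; adjusted p = 0.614 with an estimated correlation). With a term for replicate number their adjusted p was 3.65e-08, or 0.0198 with an estimated correlation. Interferon-stimulated genes (median 0.39, 2 higher adjusted over the list alone, camera adjusted p = 1.51e-06) and cholesterol genes (median 0.27, 0 over the list alone, camera adjusted p = 0.000203) were higher, with 0 called and adjusted p = 0.449 with an estimated correlation. So were genes of resting cells and homing (median 0.30, camera adjusted p = 0.0211, or 0.0565 with a term for replicate number; adjusted p = 0.614 with an estimated correlation) and cell cycle genes (median 0.19, camera adjusted p = 0.0211; adjusted p = 0.616 with an estimated correlation), with 0 members called and 0 adjusted over the list alone. The other 7 lists had camera adjusted p from 0.0572 to 0.74. Adjusted over the list alone they gave 3 Treg identity, 1 NF-kB (Rel itself) and 2 chemokine receptor genes lower, and 2 early T cell receptor genes higher and 1 lower. Chemokine receptor and cyclic AMP genes had medians below 0 and means above it. Early T cell receptor genes were higher with the term (adjusted p = 0.0317, or 0.511 with an estimated correlation) and turned to lower without both libraries numbered 3 (adjusted p = 0.939). A library numbered 3, which lay towards rTregs, stood in both the c-Rel-deficient (n = 2) and the WT group (n = 3). It weighs more in the smaller group, which can lower effector genes and raise resting genes in the main test.

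Limma called 0 genes in c-Rel-deficient aTregs, with 717 at an unadjusted p under 0.05. With a term for replicate number it called 36 genes higher and 8 lower, among them Tyrobp (3.78, SE 0.22, adjusted p = 0.000334), Il21 (2.40, SE 0.19, adjusted p = 0.00256), Rel (-3.02, SE 0.46, adjusted p = 0.0379) and Klrg1 (-2.20, SE 0.26, adjusted p = 0.0097), but 0 without both libraries numbered 3. Without c-Rel-deficient replicate 2 it called 13, all lower, and without WT replicate 3 it called 2, Sgk3 and Sema4a, named because the count is small. The authors' deposited table calls 59 higher and 18 lower, of which 50 were tested in limma, all of the same sign, and 17 were called with the term for replicate number.

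**Figure D4:**
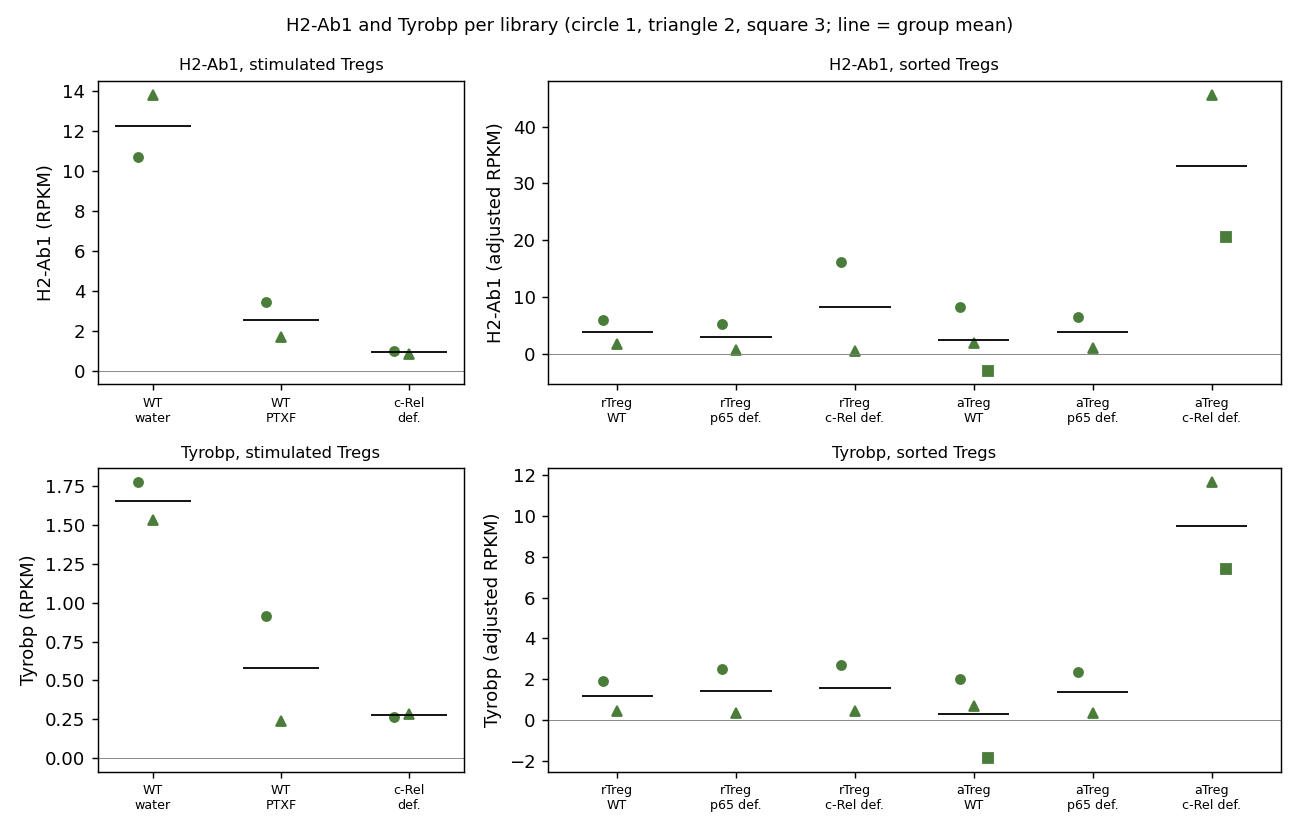
H2-Ab1, a class II antigen presentation gene, and Tyrobp in each library (vertical axis, RPKM, adjusted RPKM in the sorted set) by group (horizontal axis), with symbols for replicate numbers and a line at each group mean. H2-Ab1 is 45.6 and 20.6 in c-Rel-deficient aTregs against -3.00 to 8.24 in WT aTregs, and 1.00 and 0.808 against 10.7 and 13.8 in stimulated Tregs.

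The direct contrast of p65 loss with c-Rel loss asks whether the subunits act differently. In rTregs limma called 0 genes, also 0 with a term for replicate number, with 215 at an unadjusted p under 0.05. Cell cycle genes were higher without p65 than without c-Rel (24 of 24 above 0, median 0.42, camera adjusted p = 1e-14) as were interferon-stimulated genes (23 of 24, median 0.32, camera adjusted p = 7.69e-09), both with adjusted p = 0.475 with an estimated correlation. Treg identity genes were also higher (15 of 18, median 0.29, camera adjusted p = 0.00132) and NF-kB genes lower (18 of 24, median -0.13, camera adjusted p = 0.0207), both with adjusted p = 0.494 with an estimated correlation. Limma called 0 members of these lists, and 1 NF-kB gene, Rel itself, higher without p65, adjusted over the list alone (NF-kB list without Rel and Rela, adjusted p = 0.00216). The other 9 lists had camera adjusted p from 0.0595 to 0.967. B cell markers were lower without p65 than without c-Rel (6 of 6, median -0.53), as were erythroid markers (3 of 3, median -0.32). Changes by p65 loss and by c-Rel loss had an r of 0.692 across genes in rTregs, beside 0.499 in simulations of unchanged groups against shared WT libraries, and of 0.356 beside 0.396 in aTregs. The covariances were 0.0516 beside 0.0332 and 0.0281 beside 0.0221. The simulations drew libraries independently, while p65-deficient and c-Rel-deficient rTreg libraries of the same number had deviations from group means correlated at 0.442. This may raise r and covariance in rTregs without a shared effect.

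In aTregs limma called 0 genes between p65 loss and c-Rel loss, with 634 at an unadjusted p under 0.05, and with a term for replicate number 3 higher and 43 lower without p65, but 0 without both libraries numbered 3. It called 1 gene without p65-deficient replicate 1, Ifi208, and 2 without c-Rel-deficient replicate 2, Klrg1 and Tnfrsf8, named because the counts are small. Effector Treg genes were higher without p65 than without c-Rel (20 of 25 above 0, median 0.45, 6 higher adjusted over the list alone, camera adjusted p = 3.71e-08, or 0.118 with a term for replicate number; adjusted p = 0.48 with an estimated correlation). Cytokine and lineage factor genes were lower (11 of 12 below 0, median -0.96, 5 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.000213; adjusted p = 0.48 with an estimated correlation), and with a term for replicate number the adjusted p was 3.74e-15, or 0.00448 with an estimated correlation. Treg identity genes (median 0.28, camera adjusted p = 0.00115, or 0.15 with the term) and glycolysis genes (median 0.09, adjusted p = 0.00127, or 0.0529 with the term) were higher. NF-kB genes (median -0.14) and early genes of T cell receptor stimulation (median -0.06) were lower, each with a camera adjusted p of 0.0327. Cell cycle genes were higher (median 0.14, camera adjusted p = 0.0274) but turned to lower with the term (adjusted p = 0.196). With an estimated correlation these 5 lists had adjusted p from 0.48 to 0.683, and adjusted over the list alone 1 NF-kB gene, Rel itself, and 1 glycolysis gene were higher without p65 (NF-kB list without Rel and Rela, adjusted p = 0.0139). The other 6 lists had camera adjusted p from 0.198 to 0.65, and chemokine receptor and interferon-stimulated genes had medians and means of opposite sign. With the term resting genes turned to higher (median 0.35, adjusted p = 0.000161, or 0.209 with an estimated correlation) and interferon-stimulated genes were higher (median 0.24, adjusted p = 0.0014, or 0.364). Markers of other cells were lower without p65 than without c-Rel: B cell, class II genes included (4 of 6, median -2.74), NK and cytotoxic (4 of 5, median -2.54) and myeloid (2 of 3, median -1.63).

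The interaction of genotype and subset asks whether p65 loss or c-Rel loss acts differently in aTregs and rTregs. For p65 limma called 0 genes, also 0 with a term for replicate number, with 237 at an unadjusted p under 0.05 (76 without p65-deficient rTreg replicate 1, 2214 without WT rTreg replicate 2). The difference from WT without p65 was lower in aTregs than in rTregs for cell cycle genes (18 of 24 below 0, median -0.47, camera adjusted p = 0.00031) and interferon-stimulated genes (median -0.23, camera adjusted p = 0.0158, or 0.256 with the term). Cholesterol genes (median 0.29, camera adjusted p = 0.00287) and Treg identity genes (18 of 18 above 0, median 0.28, camera adjusted p = 0.0411, or 0.2 with the term) went the other way. These 4 lists had adjusted p = 0.842 with an estimated correlation. With the term 3 more lists passed: resting genes higher (adjusted p = 4.41e-05), and helper T cytokines (0.00302) and effector Treg genes (0.0318) lower, with adjusted p of 0.145, 0.145 and 0.396 with an estimated correlation. Erythroid markers had a median of -1.048 (3 of 3 below 0) and B cell markers one of 0.60 (6 of 6 above 0). For c-Rel limma called 0 genes, with 497 at an unadjusted p under 0.05 (217 without c-Rel-deficient aTreg replicate 3, 2559 without WT rTreg replicate 2). With the term it called 3, Siglech (3.03, adjusted p = 0.014), Tyrobp (3.59, adjusted p = 0.011) and Stfa3 (3.64, adjusted p = 0.011), genes of dendritic, myeloid or NK cells named because the count is small, but 0 without both libraries numbered 3. Without c-Rel-deficient aTreg replicate 2 it called 2, Klrg1 and Tnfrsf8. The difference without c-Rel was lower in aTregs than in rTregs for effector Treg genes (17 of 25 below 0, median -0.45, 1 lower adjusted over the list alone, camera adjusted p = 0.00202) and higher for cholesterol genes (median 0.32, camera adjusted p = 0.0159, or 0.0966 without both libraries numbered 3), both with adjusted p = 0.755 with an estimated correlation. For helper T cytokines and lineage factors the median was 0.75 (camera adjusted p = 0.0719), and with the term an adjusted p of 3.13e-06, or 0.0369 with an estimated correlation. Early T cell receptor genes had 0.0583, 0.0451 after median-of-ratios scaling, 0.00579 with the term (0.525 with an estimated correlation) and 0.338 without both libraries numbered 3. B cell markers, class II genes included (6 of 6, median 2.17), and NK and cytotoxic markers (5 of 5, median 1.048) stood above 0, and erythroid markers below it (3 of 3, median -1.32).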

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

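The tests of the patterns weighed here were chosen after the results they measure were seen, and the interaction tests were planned.

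Cell cycle genes responded differently to p65 loss in rTregs and aTregs (median of the differences -0.47, camera adjusted p = 0.00031), as did interferon-stimulated genes (adjusted p = 0.0158), cholesterol biosynthesis genes (adjusted p = 0.00287) and Treg identity genes (adjusted p = 0.0411). With a term for replicate number the adjusted p of interferon-stimulated genes was 0.256 and that of Treg identity genes 0.2, and with an estimated correlation all 4 had 0.842. Effector Treg genes (adjusted p = 0.00202) and cholesterol genes (adjusted p = 0.0159) responded differently to c-Rel loss in the 2 subsets, with 0.755 with an estimated correlation for both and 0.0966 for cholesterol genes without both libraries numbered 3. These differences were found by the interaction test.

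Some genes differed from WT in opposite directions in every library of different settings of c-Rel loss, and the difference was not tested, since the sets were normalized separately. Bcl2l11, a death-promoting gene, was higher in stimulated Tregs (0.93) and lower in rTregs (-0.33), 1.255 apart on the log2 scale, and Cd69, an early activation marker, was higher (0.73) and lower (-0.45), 1.18 apart. Limma called none of these differences, and the authors' deposited table calls neither gene in rTregs (adjusted p = 1 for both). Antigen presentation genes were higher in aTregs and lower after stimulation: H2-Ab1 by 7.01 in all, H2-Aa by 6.48 and H2-Eb1 by 6.11. Tyrobp was 4.58 apart in the same directions, its fall after stimulation not called by the deposited table (adjusted p = 1). In WT aTregs (n = 3) H2-Aa was 0.854 ± 2.67 RPKM, H2-Eb1 1.13 ± 4.04 and H2-Ab1 2.37 ± 5.64, low beside their spread. Values below 0 were set to 0, so the sizes for these genes depend on that step and on the added 0.5.

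Antigen presentation genes were higher in c-Rel-deficient aTregs and lower in stimulated c-Rel-deficient Tregs. The median log2 difference of the B cell genes Cd79a, Cd79b and Ms4a1 in aTregs was -0.069, against 3.66 for the class II genes, which argues against B cells in the aTreg sorts, while B cells in the stimulated set were not tested and stay open. A list of dendritic cell genes was written after the pattern was seen. It had a median of 0.77 in aTregs (11 of 12 above 0) and -0.505 after stimulation (6 of 8 below 0), the latter at its bound of -0.5. Genes were used if any library of either group reached 1 RPKM. Spi1 (0.162 in WT aTregs) and Spib (0.0996), for example, thus entered through the c-Rel-deficient libraries and could only count as higher. Of the 12 genes used, 6 were also at 1 RPKM or more in WT aTregs. They differed by 0.74 (Id2, of the effector list), 0.14 (Cd86 and Pacsin1), 0.10 (Ctss and Runx2) and -0.63 (Cybb). Ctss was 297 ± 64.9 (n = 2) against 275 ± 8.35 (n = 3) and Cybb 10.99 ± 5.71 against 16.9 ± 5.92. The list therefore cannot decide whether different numbers of dendritic cells were present. The sort for YFP would be expected to remove such cells, and a change of these genes within Tregs that lack c-Rel stays open, as no test of it was run.

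Changes were smaller in stimulated c-Rel-deficient replicate 2, where Rel was 24.96, than in replicate 1, where it was 2.44. The median ratio of the changes on the linear scale, replicate 2 over replicate 1, was 0.407 over 305 genes called in the authors' deposited table, with quartiles of 0.229 and 0.64. It lies just inside the bounds of 0.4 and 0.8 set for Tregs with intact Rel in that library, and below the ratio of 0.586 for Rel itself. The genes were called from these same libraries, and that choice can itself shift the ratio, which therefore decides nothing here. Tregs that kept Rel are a candidate explanation. A weaker response of that library for another reason stays open, as does an effect of sex, since WT replicate 2 alone of the 4 libraries compared had high Xist (18.7), and no biological explanation was tested.

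Libraries numbered 3 of the sorted set, aTregs alone, lay between aTregs and rTregs. The SD over genes of the log2 difference between the gene means of numbers 3 and 2 was 0.0459, although number 2 holds both subsets. Between the subsets it was 0.439. Gene means this alike argue that an adjustment for replicate number without a term for the subset moved these libraries towards rTregs. They argue against resting cells in those sorts as the only cause. The main comparisons that use WT or c-Rel-deficient aTregs carry this shift. Whether the sorts also held resting cells could not be decided: the slope of the deposited fold changes on those of numbers 1 and 2 was 1.19, and the model terms behind the deposited values are not stated. No biological explanation was tested.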

How the results depend on the processing

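The setting without both libraries numbered 3 and the NF-kB list without Rel and Rela were chosen after the data were seen, and the others were planned. For the counts of genes and the similarity, pseudocounts of 0.1 and 1, a filter at 3 RPKM, median-of-ratios scaling and robust variance left all 13 within 1.5 times the main value or within the replicate spread. For values that moved or reversed the cause was not tested, except that leaving out libraries and testing only the groups compared use fewer samples. A lone library left in a group was assumed to vary like the other groups.

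With no filter on low values 3 genes changed by c-Rel loss in stimulated Tregs (Snora19, Mir133a-1 and Mir1967), 1 by p65 loss in aTregs (Frmd5) and 40 by c-Rel loss in aTregs. Between p65 loss and c-Rel loss in aTregs 5 differed (Frmd5, Bace2, Pparg, Cobl and F13a1). With the replicate block 1 gene changed by c-Rel loss in stimulated Tregs (Ccl22), 2077 differed between WT aTregs and rTregs, 1 changed by p65 loss (Igfbp4) and 44 by c-Rel loss in aTregs, 46 differed between the 2 losses in aTregs, and 3 (Siglech, Tyrobp and Stfa3) differed in the c-Rel effect between subsets. With only the groups compared 4 genes changed by c-Rel loss in stimulated Tregs (Igj, H2-Ab1, H2-Aa and H2-Eb1), and 208 differed between WT aTregs and rTregs. Without both libraries numbered 3 the latter was 2199, and every other comparison of the sorted set gave 0. Genes listed for counts of 5 or fewer were chosen after their values were seen.

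Leaving out each library in turn gave 2217 to 3644 genes for pentoxifylline, 0 to 280 for c-Rel loss in stimulated Tregs and 3076 to 4067 between the 2. It gave 84 to 2960 between WT aTregs and rTregs, 0 to 2 for p65 loss and 0 to 13 for c-Rel loss in aTregs, 0 to 2 between these, and 0 to 2 for the c-Rel interaction. Counts at an unadjusted p under 0.05 depended on single libraries too: without WT rTreg replicate 2 they rose to 2653 and 2770 for p65 and c-Rel loss in rTregs, and to 2214 and 2559 for the interactions. They ran from 318 to 1286 for c-Rel loss in stimulated Tregs, 263 to 633 for p65 loss and 341 to 1021 for c-Rel loss in aTregs, and 119 to 434 and 424 to 608 between the losses in rTregs and aTregs. The similarity of pentoxifylline and c-Rel loss ran from -0.136 to 0.182 and so reversed without water replicate 1.

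Of the gene lists under an adjusted p of 0.05, all 66 lost it with an estimated correlation, 2 with scaling, 8 with the replicate block and, of 48 in the sorted set, 5 without both libraries numbered 3. Another 14 lists passed with the block and not in the main test, 13 of them in the direction of the main test, and 3 passed without both libraries numbered 3 but neither with the block nor in the main test. The NF-kB list kept its call without Rel and Rela in all 6 comparisons where it had one. Cell cycle genes between p65 loss and c-Rel loss in aTregs reversed, with adjusted p = 0.196 with the replicate block and 0.506 without both libraries numbered 3.

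Of the 73 named genes called by limma 45 kept the call without each library, 28 lost it without at least 1, and 0 turned sign. Genes that reversed had not been called: Foxp3 under pentoxifylline (-0.26 to 0.066), between subsets (-0.16 to 0.28) and with p65 loss in aTregs (-0.49 to 0.042). Rela also reversed under pentoxifylline (-0.061 to 0.076), with c-Rel loss in rTregs (-0.0067 to 0.045) and with c-Rel loss in aTregs (-0.012 to 0.054), as did Rel with p65 loss in rTregs (-0.71 to 0.18). Of 146 results for named genes, 4 lost their call with a pseudocount of 0.1, 8 with no filter, 19 with only the groups compared, 1 at 3 RPKM and 1 with robust variance, while 7 gained one with the replicate block, 3 with only the groups compared and 1 with no filter, in the same direction. Leaving out a library gave a call to a named gene 24 times, 23 of them without stimulated c-Rel-deficient replicate 2, and took one away 83 times. Depth limits low values in the stimulated set, and in the sorted set it is unknown.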

Other observations

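The test reported here was written before its result was seen. Il2, the growth factor that Tregs usually do not make, was 11.5 and 3.41 RPKM in stimulated c-Rel-deficient Tregs and 1.84 and 3.89 in WT with water, which overlap, and 2.75 and 1.34 in c-Rel-deficient aTregs against 0.847, 0.169 and -0.359 in WT. Il21 was 2.40 and 1.23 after stimulation in the libraries labelled c-Rel-deficient, of which the second held Rel at 24.96, and 0.244 and 0.364 in WT with water. Both genes were chosen after their values were seen.

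Of 270 genes that the authors' deposited table calls after c-Rel loss in stimulated Tregs, 56.3% had the same sign in c-Rel-deficient aTregs. Random lists matched on expression had a median of 54.8%, and the share stood at percentile 68.4 of 10000, which leaves a shared direction undecided.

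Sex-linked genes differed between stimulated replicates. Xist, transcribed from the inactive X, was 0.0153 and 18.7 RPKM in water replicates 1 and 2, 0.00965 and 22.3 with pentoxifylline, and 0.0111 and 0.0209 in c-Rel-deficient Tregs. Ddx3y, on the Y chromosome, was 27.8 and 2.73 with water, 39.7 and 6.33 with pentoxifylline, and 23.7 and 27.7 in c-Rel-deficient Tregs. The c-Rel-deficient libraries thus resemble water replicate 1 alone, and the c-Rel comparison and the ratio of its changes between replicates carry this imbalance. Klrb1c, an NK cell gene, was 25.05 in c-Rel-deficient aTreg replicate 2 and -0.0212 in WT aTreg replicate 2.

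The homing-list gene Igfbp4 was 273 in WT aTreg replicate 3 and 366 in c-Rel-deficient aTreg replicate 3, against 26.3 and 32.4 in WT aTreg replicates 1 and 2 and 41.5 in c-Rel-deficient aTreg replicate 2.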
